A study of Mus musculus with 2 samples.

How the data were processed

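Total RNA of heart samples from female 5xFAD/CAST mice was sequenced from 300 ng of RNA per library with a directional kit and ERCC spike-ins, per the labels. The 2 libraries formed 1 group and were taken as replicates from the labels, with 0 groups to set against it, so that the comparisons made were between replicates, between gene lists and between quantifications. For each library the authors deposited a gene table and a transcript table derived from an alignment to the transcriptome, and a transcript table derived directly from reads, all on mm10 with the GENCODE M21 annotation. Expected counts (estimated counts in the direct tables) were deposited by the authors as unnormalised estimates of reads per gene or transcript, per the file headers. TPM values were deposited as scaled over all genes or transcripts and spike-ins of a table, with lower and upper credibility bounds of the TPM beside them from the authors' quantifier. The percentage of a gene's TPM on each transcript was deposited by the authors in the alignment-based transcript tables, per the file headers. The aligner, the quantifiers and their versions were not given in the sources used here, and neither was whether counting used the strand, so that values of overlapping genes are uncertain.

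All 55536 gene identifiers of the tables matched the annotation, and 141767 of 141862 transcripts were in both kinds of table. TPM values were rescaled to endogenous genes, leaving out spike-ins, the phiX174 sequence and 26248 entries with numeric identifiers that held 0 or 1 counts. Estimated counts of the direct tables were summed over the transcripts of a gene. Depth was 45599940.0 and 40801299 expected counts, of which 45411752 and 40655660.0 were endogenous. A count of 0 allows up to 3 counts. Expected counts were rounded to whole numbers for the count models. Libraries were scaled with TMM in edgeR 4.0.16 under R 4.3.3, and log2 ratios, replicate 2 over replicate 1, carried a prior count of 2. Folds and their 95% counting intervals came from the scaled counts, and they cover counting error only. The common biological coefficient of variation was estimated in edgeR over genes with a mean count of at least 10. Differences were counted among genes with a mean count of at least 50 and called at 2-fold. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

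The 37 lists of 456 genes, for heart muscle, other cell types, carried-along tissues and cell states, the groups and the main settings were fixed before the data were examined. Of the list symbols 2 were not in the tables and 4 had more than 1 gene identifier, of which the one with the highest mean count was used. A list's median TPM over members with at least 1 TPM in either library was set against 10000 random lists of the same size from genes passing that filter, and its median log2 ratio over members with a mean count of at least 10 against 10000 random lists matched in 10 expression bins, with the central 95% as the range. A list needed 3 members. Transcript tables were compared over genes with at least 5 TPM in both libraries in either kind of table, with a pseudocount of 0.5 in their ratio, and a gene's main transcript was its most abundant one. Shared sequence was measured as the share of 31-base words of a gene's transcripts found in another gene.

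Genes were named by rule. It took the 15 nuclear protein-coding and 3 mitochondrially encoded genes with the highest TPM, the 4 highest members of each list (2 for carried-along tissues) and any member of a list outside its range. It also took the 12 largest log2 ratios in each direction with a mean count of at least 100, the 5 largest differences between tables in each direction, the transcripts of Ttn, Tpm1, Tnnt2, Ldb3, Camk2d, Mef2c, Ryr2, Pkm, Fn1 and App, and a fixed set of single genes that included Myh6, Myh7, Nppa, Nppb, Xist, App and Thy1.

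The steps were tested on simulated data of 2 libraries with a true coefficient of variation of 0.08, which was estimated as 0.0799. The 2-fold rule took in 2% of genes set 1.5-fold apart, 46% of those set 2-fold apart, 100% of those 4-fold higher and 98% of those 4-fold lower, and 1 of 12277 unchanged genes. Of simulated lists, 20 of 20 shifted ones and 4 of 60 unshifted ones lay outside the range. Alternatives were other scalings (size factors of DESeq2 1.42.0, library size, spike-in totals), other minima for counts and TPM, other prior counts and fold thresholds, random lists without matching, the direct tables and each library alone. Transcripts of the human transgenes and differences between CAST and reference alleles were not analysed here.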

Results

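Total RNA was sequenced from heart samples of adult female mice of a cross between 5xFAD and CAST at 8 to 10 months of age. 5xFAD mice carry mutant human transgenes driven by the Thy1 promoter and serve as a model of Alzheimer's disease, and CAST is a wild-derived inbred strain. The series held 1 group of 2 biological replicates, so no contrast between groups could be made, and the questions open to these data were which genes the heart samples expressed, how far the replicates lay apart and how far the quantification set the values. The labels gave each replicate its own biosample but the same donor identifier, so an SD measured only the spread between these libraries. Replicate 1 held 45599940.0 and replicate 2 held 40801299 expected counts. ERCC spike-ins, synthetic RNAs added to each sample, took 0.412% and 0.357% of the counts, with 66 and 64 of 96 detected. Levels are given as mean ± SD of n = 2 libraries in TPM, a relative abundance corrected for transcript length, over endogenous genes unless stated otherwise.

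The most abundant nuclear protein-coding transcripts were those of the contractile apparatus and of energy supply. Of nuclear protein-coding genes, the ventricular myosin light chain Myl2 (7882 ± 629 TPM), the adult myosin heavy chain Myh6 (7725 ± 27.7), the oxygen-binding protein myoglobin, Mb (6771 ± 267), and the sarcoplasmic calcium pump Atp2a2 (4385 ± 146) were the most abundant. They were followed by the troponin and tropomyosin genes Tnni3 (3922 ± 142), Tnnt2 (3644 ± 29.6) and Tpm1 (3552 ± 392), the light chain Myl3 (3544 ± 97.4) and cardiac actin, Actc1 (3488 ± 1021). This order holds for the alignment-based tables, since in the direct tables Myl2 stood at 13547 TPM, Mb (7238 and 7655) lay above Myh6 (6332 and 6227), and Tnnt2 (4718 and 4873) lay above Atp2a2 (3994 and 3872). The ATP synthase subunit Atp5b, the calcium pump inhibitor Pln, troponin C (Tnnc1), the fatty acid binding protein Fabp3, the ADP/ATP carrier Slc25a4 and the cytochrome oxidase subunit Cox6b1 lay between 1646 ± 35.2 and 2831 ± 48.6 TPM. These 15 genes made up 17.0% ± 0.301 of the TPM of nuclear protein-coding genes. Of all endogenous TPM they took 5.57% in replicate 1 and 5.95% in replicate 2. The mitochondrially encoded respiratory chain genes mt-Co1 (34752 ± 771), mt-Co3 (30324 ± 1451) and mt-Atp6 (20467 ± 863) stood above every nuclear protein-coding gene. The levels of mt-Co3 and mt-Atp6 are uncertain because chromosome 1 carries near-identical copies of both, and part of mt-Co1 is copied there as well.

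**Figure D1:**
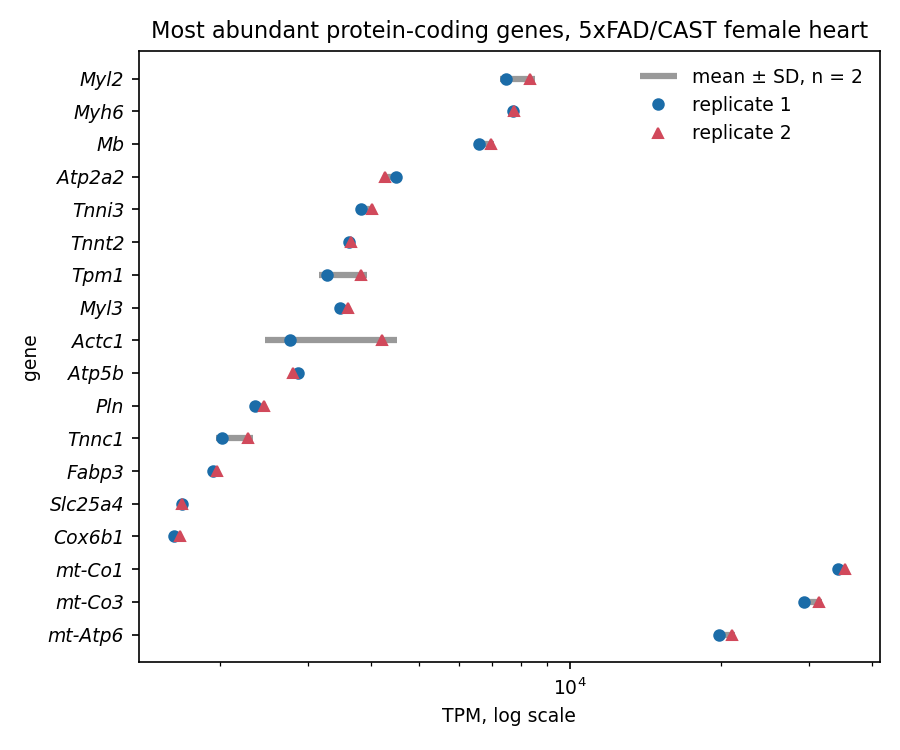
Levels of the 15 most abundant nuclear protein-coding genes and 3 mitochondrially encoded genes in TPM of the alignment-based tables on a log axis, with a point for each of 2 replicates and a bar for mean ± SD. Actc1 had the widest bar (3488 ± 1021), and Myh6 differed little between the replicates (7725 ± 27.7).

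Mitochondrially encoded protein genes took 16.9% ± 0.485 of the endogenous TPM and nuclear protein-coding genes 33.9% ± 1.00. The 2 mitochondrial ribosomal RNAs, mt-Rnr1 and mt-Rnr2, took 23.8% ± 1.77, and they and the next pair are named because their levels were seen to be high. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA that had identical estimated counts and so cannot be separated, each stood at 68725 ± 14477 TPM and led the class of miscellaneous RNAs (15.7% ± 2.94). Pseudogenes took 7.01% ± 0.0360, long non-coding RNAs 1.11% ± 0.0498 and small nuclear and nucleolar RNAs 1.07% ± 0.268. Most of the pseudogene share lay on chromosome 1 copies of mitochondrial genes, Gm28661 (31914 ± 676 TPM), Gm10925 (15065 ± 131) and Gm29216 (11673 ± 290). They share sequence with mt-Co2, mt-Atp6 and mt-Co1, so the shares of pseudogenes and mitochondrially encoded protein genes are uncertain against each other. Of the share annotated as long non-coding, Gm26917 alone held 5091 ± 116 TPM and Gm42418, its neighbour on chromosome 17, held 1208 ± 201. What the reads of this pair derive from was not tested. These genes and the chromosome 1 copies are named because their levels were seen. By expected counts, which are not divided by gene length, the share of mitochondrially encoded protein genes was 12.5% ± 0.0878. On that measure nuclear protein-coding genes took 55.1% ± 0.305, mitochondrial ribosomal RNAs 24.4% ± 1.20 and long non-coding RNAs 2.00% ± 0.146. Miscellaneous RNAs took 2.69% ± 0.567, pseudogenes 3.11% ± 0.0614 and small nuclear and nucleolar RNAs 0.0762% ± 0.0183. The larger TPM shares of these 3 classes thus depend on division by length. At a threshold of 1 TPM, 11716 genes were detected in both libraries, of which 10784 were protein-coding, while 289 passed in replicate 1 alone and 420 in replicate 2 alone.

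Myh6, the fast adult ventricular heavy chain, exceeded Myh7, the slow and fetal form, by a TPM ratio of 9.58 ± 0.153. That ratio was 22.1 ± 0.172 by expected counts and 5.68 ± 0.0870 in the tables derived directly from reads. The natriuretic peptide genes Nppa and Nppb, which heart muscle induces under load, stood at 720.5 ± 310.4 and 49.5 ± 21.1 TPM. The mouse amyloid precursor gene App was expressed at 40.01 ± 1.41 TPM and Thy1, whose promoter drives the transgenes, at 4.43 ± 0.603. The transcripts of the human transgenes were not analysed here, and the annotation used is of the mouse. Whether reads of the transgenes were counted within App or Thy1 was not tested. Xist, the RNA that silences an X chromosome in females, stood at 15.9 TPM in replicate 1 and 14.1 in replicate 2. The 1570 annotated genes of the Y chromosome together held 50 counts in replicate 1 and 51 in replicate 2.

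Against random lists of equal size, 12 of 31 fixed gene lists lay above the central 95% of median levels and 2 below. Sarcomere and Z disc genes had a median of 909 TPM, nuclear oxidative phosphorylation genes 800.03, glucose uptake and glycolysis genes 296, fatty acid uptake and oxidation genes 218 and calcium handling genes 125. In these lists Cox4i1, Atp5a1, Gapdh, Aldoa, Ldhb, Lpl, Cd36 and Hadhb, all enzymes, subunits or carriers of energy metabolism, stood between 616 ± 5.45 and 1606 ± 28.4 TPM. The ryanodine receptor Ryr2 and the histidine-rich calcium binding protein Hrc stood at 366 ± 12.01 and 356 ± 6.36. Mitochondrially encoded proteins (median 9738 TPM), ribosomal proteins (197), cardiac stress genes (105), heat shock genes (91.6), non-coding RNAs (58.2), erythroid genes (53.0) and endothelial genes (21.8) were the other lists above that range. The erythroid median was 101.3 TPM in replicate 2 alone and the non-coding RNA median 100.8 in replicate 1 alone, both still above the range. These medians cover fewer members that passed the filter, 7 erythroid genes instead of 8 and 9 non-coding RNAs instead of 10. They are therefore not a measure of a difference in level between the libraries. Cryab, a small heat shock protein of muscle, reached 1149.8 ± 68.7 TPM and the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 872 ± 112, 732 ± 77.9 and 607 ± 105. Reads of Hba-a1 and Hba-a2, which are near-identical, may have been split by the estimate. Rps14, Rpl13a, Rpl7 and Rpl8, parts of the ribosome, lay between 223 ± 16.6 and 347 ± 8.58. The endothelial genes Egfl7, Eng and Vwf lay near 40 TPM, at 40.5 ± 1.44, 39.5 ± 2.61 and 38.5 ± 8.23, and the endothelial and adipocyte lipid chaperone Fabp4 reached 217 ± 26.0.

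Interferon-stimulated genes (median 1.43 TPM, percentile 0.04, led by Ifitm3 at 31.5 ± 4.22) and adipocyte genes (2.60 TPM, percentile 1.87, led by Cfd at 18.4 ± 4.60) lay below. The interferon call held in either library alone, while the adipocyte list was inside the range in each library alone. Its median was 4.79 TPM over 8 members in replicate 1 (percentile 20.9) and 3.42 TPM over 10 members in replicate 2 (percentile 5.36). These medians cover different members. Epicardial (percentile 1.97) and skeletal muscle genes (1.495) lay below in replicate 2 alone, and glucocorticoid genes above in replicate 1 alone (98.5). Without a filter on low values, neither the interferon-stimulated nor the adipocyte list lay below (percentiles 53.7 and 72.5). The other 17 lists were inside, with medians of 1.81 TPM for Schwann cells and neurons, 2.51 for the conduction system, 2.56 for skeletal muscle, 2.84 for epicardium and mesothelium and 3.79 for valve tissue. Macrophage genes had a median of 5.15 TPM (Lyz2 37.0 ± 3.51), class II antigen presentation 5.47 (Cd74 17.8 ± 3.46), replication-dependent histones 6.58 (Hist1h1c 66.3 ± 0.881), pericytes and smooth muscle 8.17 (Abcc9 82.8 ± 0.264) and immediate early genes 8.50 (Klf2 22.9 ± 1.70). Amyloid precursor processing genes had a median of 11.7 TPM (Apoe 103 ± 3.97), fibroblast genes 12.4 (Gsn 267 ± 0.692), clock genes 13.4 (Dbp 62.1 ± 4.24), sex-linked genes 14.5 (Ddx3x 65.4 ± 3.42), unfolded protein response genes 16.1 (Hspa5 249.7 ± 19.6), glucocorticoid and fasting response genes 16.5 (Txnip 110.5 ± 1.56) and atrial genes 17.9 (Nppa 720.5 ± 310.4). Too few members were detected for lymphocytes (2 of 14), thymocytes (0 of 8), neutrophils and mast cells (2 of 10), liver (2 of 8), cell cycle (1 of 10) and lung (0 of 8). The lung genes Lamp3 and Ager, markers of the alveolar epithelium, had 5 counts or fewer in each library, while Ighm, an antibody heavy chain gene of B cells, reached 3.72 ± 0.944 TPM.

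Levels in the replicates lay close together, with a Pearson correlation of 0.991 and a Spearman correlation of 0.987 across 15785 genes, which are not independent replicates. Actc1 (2766 and 4210 TPM), Nppa (501 and 940) and Myl7 (249 and 374) were abundant genes with a wider gap, whereas Mb (log2 ratio of normalised counts -0.00), Tnni3 (0.00) and Pln (-0.00) had almost the same level. The median absolute log2 ratio was 0.11 (1.08-fold), and the counts differed by more than sampling noise (chi-square per degree of freedom 14.2), which does not show whether the samples came from separate animals. The common biological coefficient of variation was 0.0905 over genes and 0.0733 over protein-coding genes. For the 33 spike-ins with a mean count of at least 50 it was 0.0150. Spike-in ratios deviated from their median by 0.06 (median absolute log2) and genes of matched counts by 0.11.

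Between the libraries, 73 of 12492 genes with a mean count of at least 50 lay at least 2-fold apart, 31 higher in replicate 2 and 42 higher in replicate 1. Among protein-coding genes, Nmrk2, a nicotinamide riboside kinase of striated muscle, was 2.80-fold higher in replicate 2 (95% counting interval 2.37 to 3.33, 2.87 against 8.43 TPM). Cnn1, the smooth muscle calponin, was 2.10-fold higher (1.57 to 2.82), Bmp10, a growth factor secreted by the atria, 2.09-fold (1.95 to 2.25) and Tfrc, the transferrin receptor, 2.06-fold (1.90 to 2.23). Fosb, an AP-1 transcription factor induced within minutes of a stimulus, stood at a ratio of 0.242 of replicate 2 over replicate 1 (0.191 to 0.302, 3.18 against 0.805 TPM). On mm10, Nmrk2 lies on chromosome 10 from 81198170 to 81202051, Bmp10 on chromosome 6 from 87428994 to 87437677 and Fosb on chromosome 7 from 19302696 to 19310051.

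Many other genes at the extremes have close copies or overlap another gene, so their values are uncertain. Aarsd1, an editing enzyme of alanyl-tRNA, was lower in replicate 2 (ratio 0.406) and Gm27029, a gene model that spans it on chromosome 11, was higher (3.04). The spliceosomal RNA genes Gm23444 and Gm23472 shared identical estimated counts (2271 and 486), as did the pseudogenes Gm10240 and Gm13370 (484 and 70.7). The small nuclear RNA Gm24497 had 2.75 counts in replicate 1 and 1349 in replicate 2, and the protein-coding 1700047I17Rik2 had 0 and 292, yet both had 0 TPM in the direct tables of both libraries. The pseudogenes Gm10222 (ratio 0.0997) and Gm10132 (0.146), the small nuclear RNA Gm22513 (0.432) and the gene models Gm21887 (0.266), Gm20605 (0.373) and Gm14288 (0.427) were higher in replicate 1. Gm10163, Rps12l1, Gm4366, Gm5884 and Gm49358, of which all but Gm49358 are processed pseudogenes, were 2.05-fold to 2.57-fold higher in replicate 2. By class, 32 of 11634 protein-coding genes, 22 of 340 pseudogenes, 16 of 65 small RNAs and 3 of 453 other genes lay 2-fold apart. Of the 32 protein-coding genes, 13 had at least 50% of their 31-base words in another gene, against 2.76% of those less than 2-fold apart. The protein-coding genes split into 17 higher in replicate 2 and 15 higher in replicate 1, whereas 15 of the 16 small RNAs were higher in replicate 1. These small RNAs are not independent, since some had identical estimated counts, such as Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 (188.4 and 0). Of the 73 genes, 25 were also 2-fold apart in the direct tables, among them 20 of the protein-coding genes and 0 of the small RNAs. The count for small RNAs could hardly be otherwise, since the direct tables listed nearly all of them at 0 or under 1 TPM. Rn7s6, at 7.03 and 3.39 TPM there, had a log2 ratio of -1.01 but missed the minimum count. With 1 library against 1, no test or replicate check of these differences exists, and the intervals cover counting error only. Scaling to spike-in totals moved the median of all genes by 0.22 on the log2 scale and the split to 73 genes higher in replicate 2 and 27 higher in replicate 1.

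**Figure D2:**
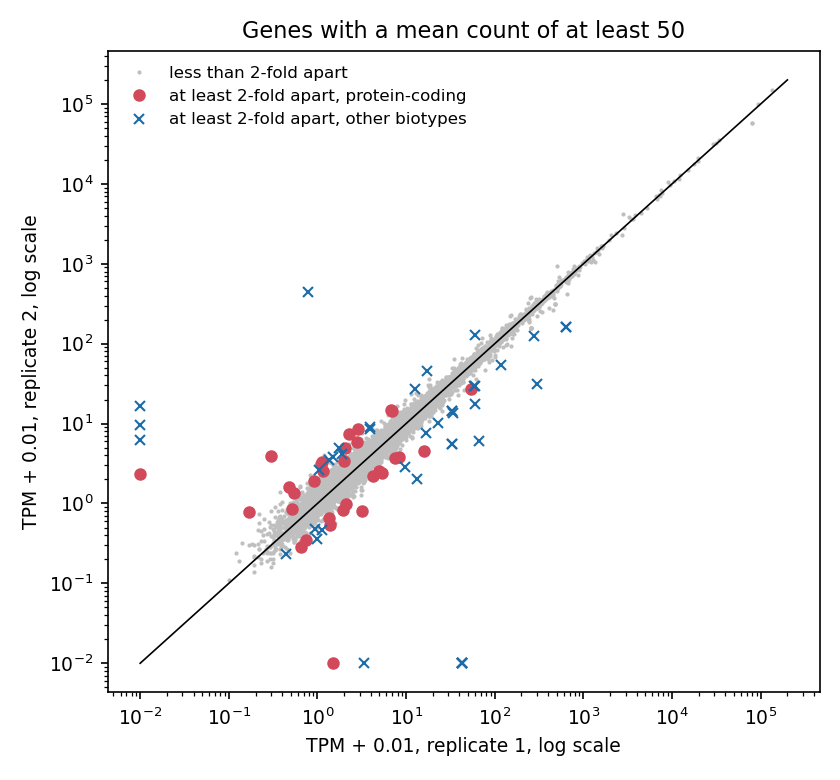
TPM + 0.01 of replicate 2 against replicate 1, both on log axes, for 12492 genes with a mean count of at least 50, with the line of equality. Coloured marks show the 73 genes at least 2-fold apart, 32 protein-coding (circles) and 41 of other biotypes (crosses).

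Fixed gene lists were next compared through their median log2 ratio, replicate 2 over replicate 1, against 10000 random lists matched on size and expression. Of 35 lists tested, 16 lay outside the central 95%, 9 higher and 7 lower in replicate 2 than matched lists, a description of these 2 libraries only. Lists of independently drawn genes would give 1.75. Members of a fixed list may vary together between any samples, which the random lists do not allow for. The value of 1.75 is therefore not the number to expect by chance for such lists. Atrial cardiomyocyte genes were higher in replicate 2 (median 0.30, 7 of 10 members), with the natriuretic peptide Nppa at 0.84, the atrial light chains Myl7 and Myl4 at 0.52 and 0.40 and Bmp10 at 1.06, while the calcium pump regulator Sln stood at 0.10. Cardiac stress genes were higher as well (0.40, 9 of 10), including Nppa, its relative Nppb (0.83), skeletal actin Acta1 (0.64) and the ankyrin repeat protein Ankrd1 (0.52), but not Myh7 (-0.06). Fibroblast and matrix genes were higher by a median of 0.24 (12 of 15), led by the matrix genes Col3a1 (0.86), Postn (0.66), Lum (0.57) and Col1a1 (0.56), beside 0.10 for the lineage marker Pdgfra and -0.11 for Tcf21. In the pericyte and smooth muscle list (0.22, 9 of 11), the contractile genes Cnn1 (1.05), Acta2 (0.90), Tagln (0.74) and Myh11 (0.49) stood beside the list members Rgs5 (0.03), Kcnj8 (-0.02) and Abcc9 (-0.07). These members of the fibroblast and smooth muscle lists were grouped after their values were seen, and no part of a list was tested by itself.

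The macrophage, class II antigen presentation, erythroid, adipocyte and cell cycle lists were also higher in replicate 2. Macrophage genes had a median of 0.20 (13 of 16), with the complement genes C1qa, C1qb and C1qc at 0.19, 0.31 and 0.23. Class II antigen presentation genes had a median of 0.34 (7 of 7), with the invariant chain Cd74 at 0.34 and H2-Eb1 at 0.59. Erythroid genes had a median of 0.17 (7 of 9), with the globins Hbb-bs at 0.20 and Hba-a2 at 0.29. Adipocyte genes had a median of 0.78 (9 of 10), with the adipokine Adipoq at 1.14 (1.09 and 3.08 TPM), the thermogenic uncoupler Ucp1 at 1.21 and the lipid droplet coat protein Plin1 at 0.91, while the lipase Lipe, which muscle also expresses, stood at -0.40. Cell cycle genes had a median of 0.83, from 3 measurable members, the proliferation genes Mki67 (0.83), Top2a (0.99) and Cenpf (0.37), of which Top2a had 14 and 27 counts.

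Of lists lower in replicate 2, fast skeletal muscle genes had the lowest median (-0.63, 9 of 9), with the troponin Tnnt3 at -0.72 (4.39 and 2.997 TPM) and the myosin Myh4 at -0.63 (3.32 and 2.24 TPM). Glucocorticoid and fasting response genes were lower (-0.31, 10 of 11), with the pyruvate dehydrogenase kinase Pdk4 at -0.72, the uncoupling protein Ucp3 at -0.59, the glucocorticoid receptor chaperone Fkbp5 at -0.45 and Zbtb16 at -0.35. Fatty acid genes were lower in 22 of 22 members by a median of -0.13, with lipoprotein lipase, Lpl, at -0.25 and the acyl-CoA thiolase Acaa2 at -0.21. Immediate early genes had a median of -0.22 (9 of 13), with Fosb at -2.03, Fos at -1.16, Zfp36 at -0.60 and Egr1 at -0.56, against Klf4 at 0.33 and Jun at 0.16. Non-coding RNAs had a median of -0.21 (11 of 12), with the nuclear RNAs Neat1 and Malat1 at -0.72 and -0.34, and unfolded protein response genes of -0.20 (9 of 11), with the glutathione-degrading Chac1 at -1.02, Herpud1 at -0.51 and the chaperone Hspa5 at -0.19. Picked after their values were seen and with no test as a set, Rn7s1 and Rn7s2 stood at -0.50, Rpph1, the RNase P RNA of the non-coding list, at -0.32 and its member Rn7sk at -0.10, while the ribosomal mt-Rnr1 and mt-Rnr2 stood at 0.06 and 0.10. The share of TPM was 17.8% in replicate 1 and 13.6% in replicate 2 for miscellaneous RNAs, 1.26% and 0.884% for small nuclear and nucleolar RNAs and 22.5% and 25.02% for mitochondrial ribosomal RNAs. Epicardial and mesothelial genes had a median of -0.16 (6 of 10), with Muc16 at -0.30 and Msln at -0.27, and this call was lost with a mean count of at least 50 (-0.086) and in the direct tables (-0.096). On the spike-in scale the medians of 5 of these lists turned positive, to 0.094 for fatty acid genes, 0.055 for epicardial genes, 0.021 for unfolded protein response genes, 0.014 for non-coding RNAs and 0.0017 for immediate early genes, while each stayed below the range of matched lists on that scale.

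The remaining 19 lists lay inside the range, and on the spike-in scale their medians are higher by about 0.22, so that the negative ones turn positive except for the neutrophil and Schwann cell lists. Sarcomere genes had a median of -0.00 (10 of 20 higher in replicate 2), calcium handling genes of -0.00, mitochondrially encoded genes of -0.02, nuclear oxidative phosphorylation genes of -0.06 (18 of 20 lower), glycolysis genes of 0.02, ribosomal protein genes of 0.01, endothelial genes of -0.06 and clock genes of 0.01. Amyloid precursor processing genes had a median of 0.03, with App at 0.00, Apoe at 0.03 and the amyloid precursor-like gene Aplp2 at 0.04. Medians were 0.07 for heat shock genes (percentile 97.1), 0.07 for the conduction system, 0.08 for interferon-stimulated genes, 0.01 for valve genes, -0.05 for sex-linked genes and -0.08 for histones. Lymphocyte genes (0.42, percentile 96.4, 7 of 14 members measurable), neutrophil and mast cell genes (-0.40, percentile 7.16), Schwann cell and neuron genes (-0.25, percentile 7.02) and liver genes (0.13, from 3 members) had wide ranges of matched lists. Against random lists without matching, the lymphocyte (percentile 99.9), neutrophil (0.16) and Schwann cell lists (0.56) lay outside, as did the neutrophil (2.29) and liver lists (median 1.43, above all matched lists) without a count filter, while the lymphocyte median was 0.019 in the direct tables. Thymocyte and lung genes could not be compared, with 2 and 0 members measurable.

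**Figure D3:**
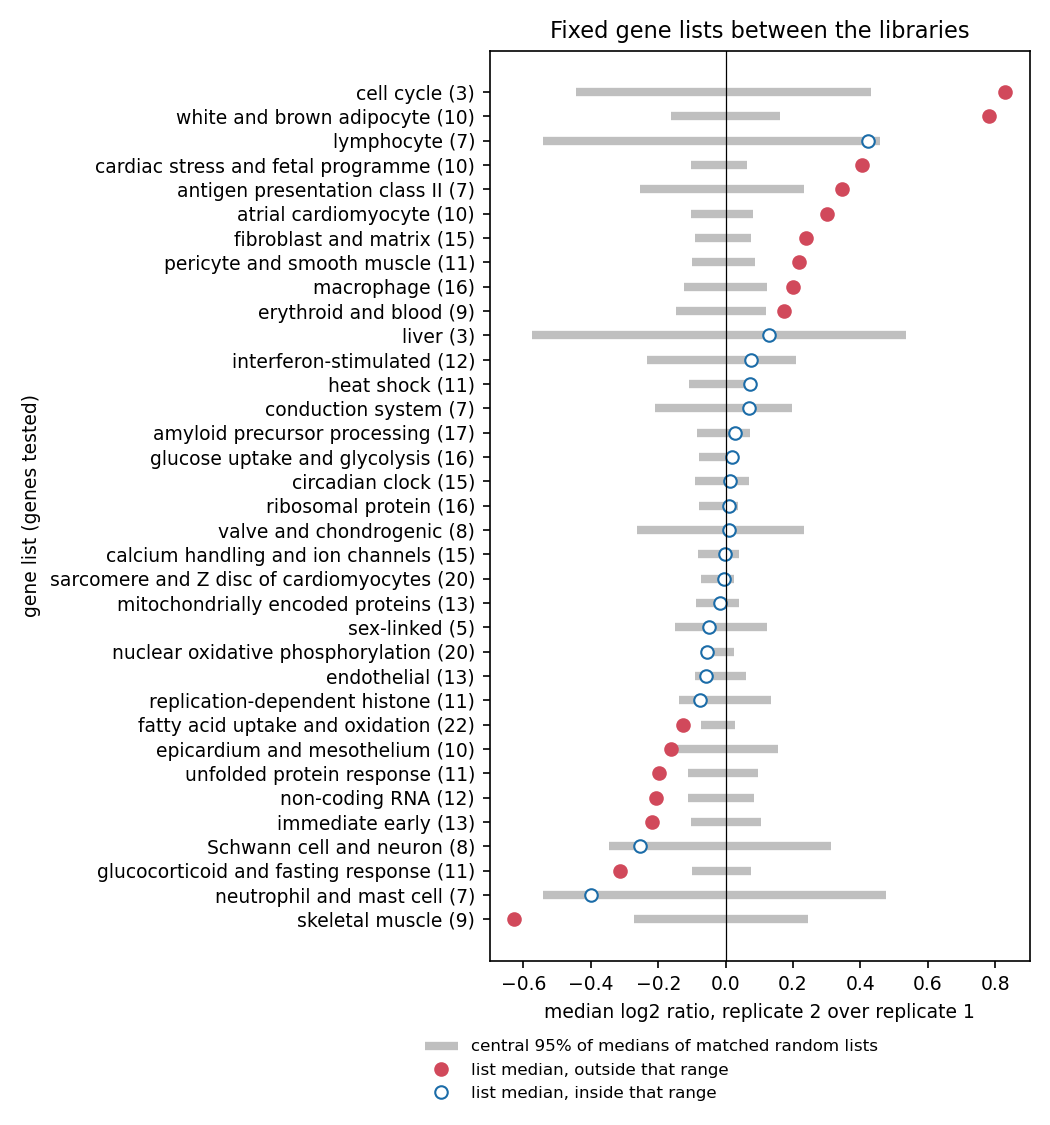
Median log2 ratio, replicate 2 over replicate 1, of 35 fixed gene lists (points, genes tested in brackets), with the central 95% of medians of 10000 matched random lists as grey bars. Filled points mark the 16 lists outside their bar, from skeletal muscle at -0.63 to cell cycle at 0.83, and on the spike-in scale the medians of 5 of these lists change sign.

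Each library had been quantified in a table based on alignments and in a table derived directly from reads, and mitochondrial genes with nuclear copies were among those whose values depended on the table. A stretch of chromosome 1 from 24612407 to 24616197 on mm10 holds 6 unprocessed pseudogenes of the mitochondrial genome. One of them, Gm10925, a copy of mt-Atp6, stood at 15065 ± 131 TPM in the alignment-based tables and at 1.76 in the direct tables. Another, Gm28437, a copy of mt-Co3, stood at 0.201 and 10836 TPM. The cytochrome oxidase subunit gene mt-Co2, chosen after its values were seen, held 802 ± 65.0 TPM beside 31914 ± 676 for its copy Gm28661, and mt-Co2 took 2.45% ± 0.143 of the summed TPM of this pair in the alignment-based tables and 19.6% ± 3.18 in the direct tables. The authors' credibility bounds for mt-Co2, 2277 to 3670.3 TPM in replicate 1 and 1846 to 3311 in replicate 2, lay above its deposited TPM in both libraries. Levels of these mitochondrial genes and their copies are therefore uncertain one by one.

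Across 7335 genes with at least 5 TPM in both libraries in either kind of table, which are not independent replicates, log2(TPM + 1) correlated between the tables with a Pearson coefficient of 0.830 and 0.842 and a Spearman coefficient of 0.889 and 0.896 in replicates 1 and 2. In both libraries 294 genes differed at least 2-fold the same way, 100 higher in the direct tables and 194 in the alignment-based ones, and they comprised 56 protein-coding genes, 121 pseudogenes, 81 small RNAs and 36 others. Besides Gm10925, the pseudogene Gm12338 (1397 ± 5.37 TPM) and the small RNA genes Gm26447, Gm24265 and Gm22988 (792 ± 93.5, 533 ± 159 and 416 ± 63.2 TPM) were listed at 0 in the direct tables. Gm19220, Gm28438 and Rpl36a-ps3 were listed at 0 in the alignment-based tables. In the direct ones Gm19220 stood at 6134 TPM in replicate 1 and 1549 in replicate 2, Gm28438 at 257 and 22.8 and Rpl36a-ps3 at 53.2 and 46.02. Nnt, the mitochondrial proton-translocating transhydrogenase, is annotated as 2 overlapping genes on chromosome 13. The one from 119335528 to 119408952 had 0 TPM in the alignment-based tables and 108 and 77.3 in the direct ones, while the other stood at 218 ± 7.65 in the alignment-based tables and 96.5 and 121 in the direct ones. The log2 ratio of the tables correlated between the libraries with a coefficient of 0.974 across genes.

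**Figure D4:**
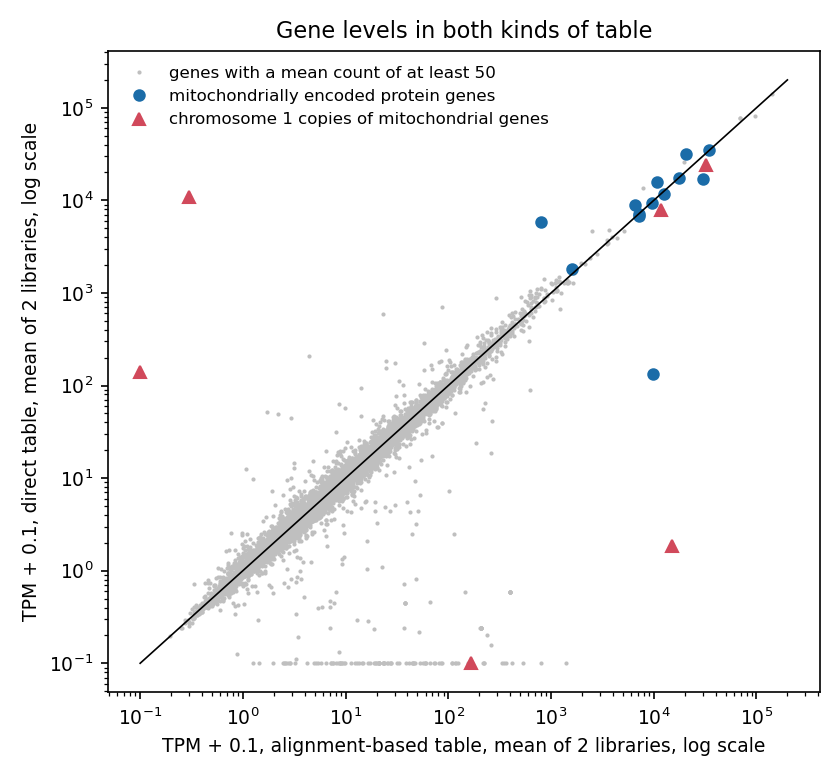
TPM + 0.1 in the direct tables against TPM + 0.1 in the alignment-based tables, means of 2 libraries on log axes, for genes with a mean count of at least 50. Mitochondrially encoded protein genes (circles) and their chromosome 1 copies (triangles) include points far from the line of equality, such as Gm10925 at 15065 and 1.76 TPM.

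Most genes used the same main transcript in both libraries, 5804 of 6355 genes with 2 or more transcripts (91.3%, Wilson 95% interval 90.6% to 92.0%), whereas the tables of a library shared it for 83.3% and 82.7%. The interval treats genes as independent draws, which they are not, and it measures no spread between samples. Ryr2 was mostly Ryr2-201 (84.7% ± 1.07 of its TPM by alignment, 85.1% ± 1.64 directly), and Pkm was split between Pkm-202 (52.7% ± 0.710) and Pkm-201 (45.9% ± 0.883). The leading transcript of the giant spring protein gene Ttn, Ttn-201, held 35.3% ± 0.353 and that of the Z disc gene Ldb3, Ldb3-203, 69.9% ± 0.317, with 37.8% ± 0.703 and 68.6% ± 0.307 in the direct tables. App was mainly App-203 (51.7% ± 2.75) and App-202 (35.4% ± 5.25), and whether reads of the human transgenes entered these shares was not tested. Other genes changed with the table. Tpm1-205 held 96.5% ± 0.201 of Tpm1 by alignment and 72.3% ± 1.14 directly, and Tnnt2-211 66.6% ± 1.47 of troponin T and 8.26% ± 10.1. For the calcium-dependent kinase gene Camk2d the share of Camk2d-202 was 40.6% ± 1.53 and 23.3% ± 3.42, and for fibronectin, Fn1, that of Fn1-203 was 15.9% ± 9.51 and 44.9% ± 9.77. The transcription factor gene Mef2c used several transcripts, of which Mef2c-212 led with 23.0% ± 0.503 and 22.5% ± 0.543.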

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

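Reads of phiX174, the bacteriophage whose DNA is added to sequencing runs as a control, were counted in the gene tables and took no part in the comparisons. Replicate 1 held 276 counts and replicate 2 held 179 of expected counts, both above the 3 counts that a count of 0 allows. No control library was available to set these counts against, and no explanation of them was tested.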

How the results depend on the processing

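Of the values that answer a comparison, 156 stayed by the rule set for each under the alternatives run, 21 moved, 2 became weaker and 5 reversed. Numbers of genes or lists stayed if within a fixed factor, and the mitochondrially encoded share and the Myh6 to Myh7 ratio if within 1 SD. For that share and that ratio, each library alone lies within 1 SD of the mean by construction, so leaving out a library could not move them. Of the values of single genes and lists among many, 167 stayed, 17 moved and 5 became stronger. The restriction to protein-coding genes, the random lists of protein-coding genes, the lists without shared genes, the spread in the direct tables, the spike-in scale for lists and the centred table ratio were chosen after the data were seen. Fewer genes were detected at 5 TPM (7106) and the mitochondrially encoded share was 12.5% by expected counts, which are not divided by length. The Myh6 to Myh7 ratio was 5.68 in the direct tables and 22.1 by expected counts, and the cause was not tested. Without a TPM filter, 20 lists lay above the range of random lists. Genes at least 2-fold apart numbered 437 at a mean count of at least 10 (183 higher in replicate 2, 254 in replicate 1), 2441 without a filter (1230.0 and 1211) and 32 among protein-coding genes (17 and 15), and the share of genes tested that lay 2-fold apart was 2.77%, 10.03% and 0.275% against 0.584%, so that it was higher where genes with low counts were included. On the spike-in scale 73 were higher in replicate 2 and 27 in replicate 1, because that scale moves every gene alike, and the medians of 5 lists lower in replicate 2 turned positive, to 0.094 for fatty acid, 0.055 for epicardial, 0.0017 for immediate early and 0.021 for unfolded protein response genes and 0.014 for non-coding RNAs. The epicardial list moved inside its range at a mean count of at least 50 (-0.086) and in the direct tables (-0.096), and the cause was not tested, while the cell cycle list had too few members for a value at that minimum and the non-coding RNA list too few among protein-coding genes. The coefficient of variation was 0.0733 over protein-coding genes, and the square root of the median gene-wise dispersion from DESeq2 was 0.0001, the lower bound it also took on simulated data, which measures no spread. Tables differed 2-fold for 577 genes at 1 TPM, and the same main transcript was found for 87.7% of genes at 1 TPM and 89.9% in the direct tables. No paired analysis was possible because there was 1 group. The effect of depth was not tested, and a count of 0 allows up to 3 counts.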

Other observations

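Transcripts of liver genes, a list of 8 with too few members for a level, differed between the libraries at low counts. Alb, the serum albumin gene of hepatocytes, had 7 counts in replicate 1 and 76 in replicate 2, a ratio of 12.04 (95% counting interval 5.57 to 30.96). Cyp2e1, a cytochrome P450 with high levels in liver, had 197 and 194. Chosen after their values were seen, the plasma protein genes Serpina1a (0 and 10.7), Apoa1 (1 and 8), Fgb (0 and 5) and Apoc3 (0 and 2) had more counts in replicate 2, whereas the carrier gene Ttr (29 and 18) and Apoa2 (8 and 6) did not. Without a count filter the median log2 ratio of the 8 genes was 1.43, outside the range of matched lists, a value that rests on genes with few counts.

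In the patterns weighed next, the tests on the atrial list, the rate of 2-fold differences by shared sequence and the test of counting noise were chosen only after the result was seen. No biological explanation was tested, since the samples form 1 group.

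Atrial genes were higher in replicate 2, with Nppa, Myl7, Myl4 and Bmp10 above Sln. The direct tables gave a median of 0.31 for the list, outside the range of matched lists on the same side, which argues against the choice of table as the cause. A larger share of atrial tissue in replicate 2 may raise all members alike, and 2 of 10 members, Bmp10 among them, lay more than 3 SD of a log2 ratio from the list's median, too few to exclude a uniform excess and too many to match it. Bmp10 and Sln lay 3.69 SD apart, but these were compared after their values were seen, so that the gap decides nothing. An excess of atrial tissue and a difference in the genes themselves, untested, stay open.

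Pseudogenes and small RNAs made up 38 of the 73 genes at least 2-fold apart between the libraries, among them Gm10222, Gm10132, Gm23444 and Gm24497. The test fixed beforehand missed its bound of 1.5, since genes 2-fold apart had at least 50% shared words 1.18 times as often as the others, and with 82.3% of the others sharing sequence the ratio could reach 1.215 at most. In a second test, chosen after that result, 10.9% of 339 genes with shared sequence and 1.52% of 66 without were 2-fold apart, a ratio of 7.20 that rests on 1 gene in the smaller class. Sampling of independent reads would put a mean of 0.0112 genes of all 405 tested 2-fold apart where 38 were seen, which argues against counting noise as the main cause but does not cover noise in dividing shared reads. Division of shared reads among copies may be a candidate explanation for part of them. However, 15 of the 16 small RNAs were higher in replicate 1, as was the share of small nuclear and nucleolar RNAs (1.26% and 0.884% of TPM). Several of these small RNAs had identical estimated counts, such as Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 (188.4 and 0), so they are not separate observations. A difference in short RNA between the libraries or samples stays open, untested.

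The subunit gene mt-Co2 stood at 802 TPM beside 31914 for its chromosome 1 copy Gm28661, while mt-Co1 reached 34752. Of the 31-base words of mt-Co2, 99.5% occur in the chromosome 1 copies, so that most reads of either may be placed on the other. The reference sequences of mt-Co2 and Gm28661 differ at 0 of 681 bases compared, which argues against base differences in the reference as what favoured the copy. How the quantifiers divided identical reads is a candidate explanation, and transcription of the copies and CAST bases were not tested.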
